A study of Mus musculus with 2 samples.

How the data were processed

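Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into exposed DNA, in limbs of mouse embryos of strain B6NCrl at 15.5 days. There were 2 biological replicates in 1 group, each a pool of embryos of both sexes, 78 embryos in replicate 1 and 62 in replicate 2. The fragmentation step was Nextera tagmentation, per the labels.

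The values used here are the authors' deposited peak lists on mm10, 3 lists per replicate and 6 lists made from both replicates. Per the deposited README texts, the lists derive from alignments to mm10, and the thresholded, pseudoreplicated and replicated lists also took a further input that is not used here. The aligner, the peak caller, their versions and the handling of the transposase offset are not given in the sources used here. The deposited lists hold, for each summit, a score, a signal value, a −log10 p and a −log10 q, all made by the authors. The score of the deposited lists was at least 540 in the thresholded lists, which in the ranked lists corresponds to a global irreproducible discovery rate (IDR, the expected share of peaks that do not recur) of 0.0500. The signal value was treated as a ratio, the fold of a peak over background as the authors computed it, and was used to describe and rank peaks within a list. The authors' −log10 p and −log10 q values were used in the same way. In the ranked lists of the pooled replicates, 16 columns that hold values of single replicates or pseudoreplicates were not assigned to a sample and were not used. No read counts or sequencing depths were among the files, so the depth per replicate is unknown, and binomial intervals below cover counting error over summits only, which are not independent of one another.

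Rows that share a chromosome, start and end are several summits of 1 region, so distinct regions and distinct summits were counted separately. The main list was the pooled IDR-thresholded list. Its summits came from the ranked list of pooled pseudoreplicates, and those of the conservative list from the ranked list of the 2 replicates. The IDR of the main list therefore does not measure recurrence between the 2 replicates. The same quantities were computed from each replicate's own list, and the mean ± SD over the 2 replicates is given where useful. With 2 replicates of 1 group no comparison between groups was possible, and the spread between replicates is known only from 1 difference.

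Positions were compared with GRCm38.p6, the assembly of mm10, and with the GENCODE M21 annotation, from which 21911 protein-coding genes with 93444 transcription start sites (TSSs) on 21 chromosomes were taken. A summit within 1000 bp of any TSS was called promoter, and the others exon, intron or intergenic in that order. For comparison, summits were placed 20 times at random on their own chromosome outside assembly gaps. Regions of the replicates were called shared with an overlap of at least 1 bp.

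A total of 25 gene lists were fixed before the data were examined. They covered tissues of the limb, other cell types that the sample could hold, tissues outside the limb, signalling pathways and the 4 Hox clusters. Of the symbols, 1 (Ahsp, erythroid) matched no gene. The share of a list's genes with a promoter summit was compared with that of all other genes by a two-sided Fisher's exact test, adjusted over the 25 lists by the Benjamini-Hochberg method. Distal summits, over 1 kb and up to 100 kb from the nearest TSS, were assigned to that gene, and a list's mean was compared with 10000 random lists matched on the length of sequence nearest to each gene, in 10 strata. Both this comparison and Fisher's exact test treat genes as independent, although neighbouring genes and the several summits of 1 region are not. Promoter CpG content is the observed over expected CpG ratio in 1001 bp around 1 TSS per gene. A total of 25 motif consensuses, also fixed in advance, were searched on both strands of 101 bp windows at summits. Each set of windows was compared with random windows outside the looser pooled peaks, drawn from 3000000 candidates and matched on GC content in bins of 5 percentage points, by a two-sided Fisher's exact test adjusted over all motifs and both classes of summit.

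Apart from those at the widest regions, genes named below follow a rule fixed in advance. It took, per list, up to 4 genes with the strongest promoter signal, up to 3 in alphabetical order without a promoter summit in the pooled list and in either replicate's list, and up to 3 with most distal summits. It also took the 10 genes of the genome with most distal summits, the 10 strongest distal peaks, and every Hox gene.

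On simulated data, lists of 25 genes with a promoter rate of 85% against 50% were called in 96% of 200 lists, and unchanged lists in 0%. Distal lists with 2-fold more summits were called in 49.5% of 200 lists, and unchanged ones in 0%, so a distal list that was not called may still differ. The simulated distal summits fell independently of one another (Poisson counts), whereas real summits cluster, several to a region. These distal rates therefore need not hold for the real lists. In each simulated run all lists were raised together, which makes the adjustment more lenient. A single list that differs may thus be called less often than these promoter and distal rates. A motif planted in 20% of windows was found in 20.8%.

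Alternatives were the conservative and the pseudoreplicated lists, summits at or above the median signal, each replicate's list alone, promoter windows of 500 and 2500 bp, 1 TSS per gene, distances of 50 and 250 kb, no matching on length, motif windows of 201 bp, flanking windows 1 kb from the summit, and other definitions of overlap. The flanking windows were not matched on GC content, so ratios against them also reflect base composition. Those added after seeing the data included CpG-matched random lists, motif backgrounds matched on GC and CpG, and 1 summit per region. Regions that passed the score limit and were missing from the thresholded list were also counted by nearest TSS after seeing the data. Sequence similarity was searched with blastn 2.17.0 at 80% identity or more. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.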

Results

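Open chromatin was mapped by ATAC-seq in mouse embryonic limbs at 15.5 days, a stage at which cartilage, bone, muscle, tendon and skin are forming. The 2 biological replicates were pools of 78 and 62 embryos. The data are lists of called peaks, with 14150 distinct regions and 32073 summits in the pooled thresholded list. Its regions had a median width of 810 bp and covered 11.6 Mb of the mm10 genome. Replicate 1 alone gave 9337 regions covering 6.82 Mb, and replicate 2 alone gave 10512 regions covering 8.35 Mb. The sequencing depth behind these lists is unknown. The design held a single group, so the comparisons are between replicates, between gene groups and between sequences.

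Peaks of the replicates were compared to see how far the same regions were open in both pools. Of the replicate 1 regions, 88.8% overlapped a replicate 2 region, and 78.1% of the replicate 2 regions overlapped a replicate 1 region. Randomly placed regions overlapped in 0.691% ± 0.0857 and 0.572% ± 0.0817 of cases (SD over 20 placements). The Jaccard index of the covered bases was 0.617. Of the 1000 strongest regions of each replicate, 99.9% lay in the other's whole list, and 64.9% of replicate 1's lay among replicate 2's 1000 strongest. The signal values of the 8288 shared regions, ranked within each list, had a Spearman correlation of 0.844 across regions, which are not independent replicates. Among the 39792 looser pooled regions, 8159 overlapped peaks of both replicates, against 2417 if the replicates' lists were independent. In the pooled list, 21% of the regions overlapped no thresholded region of either replicate.

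The number of regions depended on the tier of threshold. The conservative pooled list held 13573 regions, the replicated list 38780 and the pseudoreplicated list 39792. The pseudoreplicated lists of replicates 1 and 2 held 24441 and 28993 regions. Replicate 2 thus exceeded replicate 1 at both tiers.

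Accessible summits lay mainly at gene starts. In the pooled list 75.5% of summits were within 1 kb of a protein-coding TSS (95% Wilson interval 75.1 to 76.0), against 4.04% ± 0.130 for random positions. Introns held 8.44% of summits and intergenic sequence 15.1%, against 35.3% and 57.7% at random, and exons 0.963% against 2.93%. In the replicates' own lists the promoter share was 83.2% ± 2.29 (SD, n = 2). It fell to 46.3% in the looser pseudoreplicated pooled list.

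A promoter summit was found for 10571 of the 21911 protein-coding genes, or 48.2%. The share was 39.5% ± 1.94 in the replicates' lists (SD, n = 2), and 7778 genes had one in both. It followed the CpG content of the promoter, from 3.42% of genes in the lowest decile of CpG ratios to 89.0% in the highest decile. The median CpG ratio was 0.746 with a promoter summit and 0.244 without.

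None of the lists of the limb skeleton was called above or below other genes in the pooled list. In the cartilage list 12 of 24 genes had a promoter summit (q = 1 by Fisher's exact test), among them Sox9, the master regulator of chondrocytes, with a pooled signal of 6.60. The strongest promoter of this list was that of Col11a1, a fibrillar collagen of cartilage, with a signal of 10.9 in the region at chromosome 3 from 114029982 to 114030695. Col9a1 had 6.71 and Wwp2 6.19. Acan, the main proteoglycan of cartilage, Chad and Cnmd had no promoter summit in these lists. In the bone list 6 of 20 genes had one (q = 0.187). Col1a2, a chain of type I collagen, had a signal of 10.8 at chromosome 6 from 4504922 to 4506022, Sparc 7.45, Dlx5 5.7 and Omd 4.84, while Alpl, Bglap and Bmp2 had none. In the joint list 10 of 16 genes had one (q = 0.399), with Creb5 at 9.59, Vcan at 7.45 and Foxc1 at 7.23. Gdf5, a ligand of joint formation, Chrd and Nog had none. In the tendon list 8 of 16 genes had one (q = 1), led by Thbs2 at 11.6 and Egr1 at 10.2, while Col14a1, Fmod and Htra3 had none. In the lists of replicates 1 and 2 the share was 29.2% and 33.3% for cartilage, 15% and 20% for bone, 25% and 31.2% for joint and 25% and 37.5% for tendon, each below the 38.2% and 40.9% of all genes. In the looser pooled list the joint list was called above, with 15 of 16. Lists of this size leave smaller differences undetected.

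The limb patterning list had a promoter summit at 21 of 36 genes (q = 0.323 by Fisher's exact test). In the lists of replicates 1 and 2 it was 11 and 12 of 36, 30.6% and 33.3%, which turned the share from above that of all genes to below it. The strongest were at Pbx1, a homeodomain partner of Hox proteins, with a signal of 15.1, Tbx3 with 10.4, Gli3, the main repressor of hedgehog targets in the limb, with 10.0, and Twist1 with 9.53. Alx3, Alx4 and En1 had none. All 4 of the strongest had a promoter summit in both replicates' lists.

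In the Hox clusters the peaks called in both replicates lay at the posterior ends of HoxA and HoxD. Hoxa13, which specifies the hand and foot, had a promoter signal of 7.21 in the region at chromosome 6 from 52260678 to 52261468. Hoxd13, its counterpart in HoxD, had 9.96 at chromosome 2 from 74667713 to 74668421. No other Hox promoter was called in both replicates. In the pooled list, 6 of 11 HoxA genes had a promoter summit, with Hoxa10 at 4.70, Hoxa11 at 4.07, Hoxa7 at 3.97, Hoxa9 at 3.33 and Hoxa3 at 2.89, and Hoxa1, Hoxa2, Hoxa4, Hoxa5 and Hoxa6 had none. In the lists of replicates 1 and 2 the HoxA share was 9.09% and 27.3%, below the 38.2% and 40.9% of all genes, which turned its direction. In HoxD it was 3 of 9 in the pooled list and 11.1% in each replicate's list. Hoxd10 had 5.36 and Hoxd11 4.47 in the pooled list, neither of them called in a single replicate. Hoxd1, Hoxd3, Hoxd4, Hoxd8, Hoxd9 and Hoxd12 had none. In HoxC the pooled list had a promoter summit at 2 of 9 genes, Hoxc13 at 5.03 and Hoxc6 at 2.91, neither of them called in a single replicate. Hoxc4, Hoxc5, Hoxc8, Hoxc9, Hoxc10, Hoxc11 and Hoxc12 had none. None of the 10 HoxB genes, Hoxb1 to Hoxb9 and Hoxb13, had one (q = 0.00468), and none gained one in the looser pooled list. HoxA, HoxC and HoxD, with few genes each, were not called in the pooled list (q = 0.835, 0.253 and 0.580 by Fisher's exact test). HoxC, with 0 of 9 in each replicate's own list and in the conservative pooled list, was called below there (q = 0.0284 for replicate 1 and 0.0255 for replicate 2). Hox genes lie close together, so a summit can count for neighbours. The genes of a cluster are also not independent, as the test assumes, so these q values overstate the evidence.

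**Figure D1:**
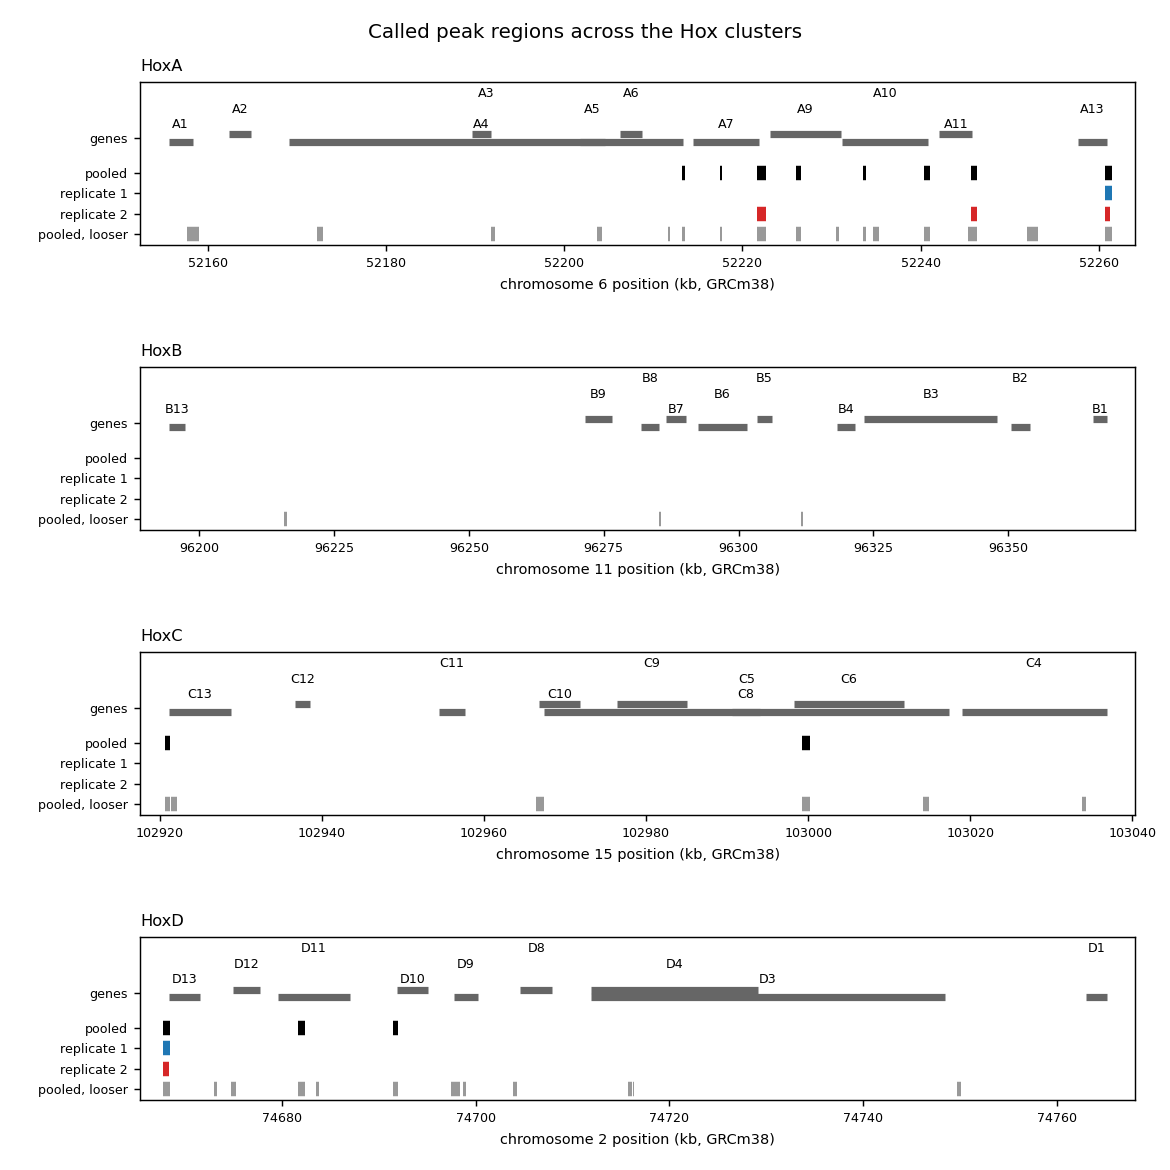
Called regions across the 4 Hox clusters, with position in kb on the horizontal axis and rows for the genes, the pooled list, each replicate's list and the looser pooled list. Blocks at the start of Hoxa13 and Hoxd13 appear in both replicates, and HoxB holds no block in the thresholded lists.

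Promoters of other cell types were mostly below the rate of other genes. Skeletal muscle had 7 of 28 genes with a promoter summit (q = 0.0233), led by Mylpf, a fast myosin light chain, at 10.9 and Six1 at 7.70, while Acta1, Chrna1 and Ckm had none. This call was lost in the list of replicate 2 alone (q = 0.170), with a promoter window of 2500 bp, and in the looser pooled list, where 17 of 28 had one. Epidermis had 3 of 26 (q = 0.000452), namely Grhl1 at 13.3, Klf5 at 12.4 and Irf6 at 5.90, and Cdh1, Dsc3 and Dsg1a had none. In the looser pooled list 17 of the 26 had one, which turned the direction of the epidermis result. Endothelium had 3 of 20 (q = 0.00551), with Ets1 at 10.9, Erg at 5.24 and Egfl7 at 3.98, and none at Cdh5, Cldn5 and Emcn. Erythroid genes had 1 of 14 (q = 0.00468), Klf1 at 1.97, and macrophage and osteoclast genes 1 of 20 (q = 0.000297), Nfatc1 at 4.43. The looser pooled list ended the endothelium and erythroid calls, with 8 of 20 and 4 of 14. Endothelium had 1 and 2 genes, erythroid 0 and 0, and macrophage and osteoclast 0 and 1 in the lists of replicates 1 and 2. Schwann cell and melanocyte genes had 8 of 20 (q = 0.580), led by Mitf, a regulator of melanocytes, at 12.9 and Mpz at 9.

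Lists of tissues outside the limb were also below other genes. Hepatocyte genes had 1 of 20 (q = 0.000297), Apoh at 8.67, with none at Afp, Ahsg and Alb. Heart genes had 0 of 15 (q = 0.000344), including Gata4, Gata5 and Gata6, but 6 of 15 in the looser pooled list, Gata4 and Gata6 among them, which ended the call. Germ cell genes had 1 of 15 (q = 0.00297), Dazl at 8.28. Central neuron genes had 3 of 20 (q = 0.00551), Syt1 at 6.74, Camk2a at 4.89 and Emx2 at 3.93, but 13 of 20 in the looser pooled list, which turned the direction. The lists of replicates 1 and 2 held 0 and 1 of them, and Camk2a and Emx2 were called in neither. None of the 1092 olfactory receptor genes had a promoter summit. Of the 11 lists called below other genes, 5 were still called in the looser pooled list.

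Above other genes were housekeeping genes, 15 of 16 (q = 0.000650), and 3 signalling pathways. Housekeeping genes were led by Pgk1 at 14.2 and Eef1a1 at 14, and Ubc had none. The BMP and TGF-beta list had 20 of 22 genes with a promoter summit (q = 0.000297), led by the receptor Tgfbr1 at 15.9 and Smad3 at 10.4, with none at Bmp5 and Gdf6. The FGF list had 14 of 15 (q = 0.00111), with Etv5, a transcription factor induced by FGF, at 13.5 and the inhibitor Spry2 at 10.7, and none at Fgf7. The hedgehog list had 12 of 14 (q = 0.0104), with the transducer Smo at 11.1 and Disp1 at 9.28, and none at Evc and Hhip. With replicate 2's list alone the FGF (q = 0.112) and hedgehog (q = 0.149) calls were lost. The hedgehog call was also lost among summits at or above the median signal, with a window of 500 bp and with 1 TSS per gene. The Wnt list had 7 of 22 (q = 0.204), with the receptors Fzd7 at 11.2 and Fzd1 at 9.39, while the inhibitors Dkk1, Dkk2 and Dkk3 had none.

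Matching random lists on CpG ratio, a choice made after seeing the data, ended several of these calls. Of the lists above other genes, housekeeping stayed above (q = 0.0278), and the BMP and TGF-beta (q = 0.0862), FGF (q = 0.0985) and hedgehog (q = 0.363) lists were no longer called. The skeletal muscle, erythroid, macrophage and osteoclast, and hepatocyte lists were no longer called below. The Wnt list fell below the 70.3% mean of its matched lists, at 31.8% (q = 0.0009999, the smallest these random lists gave). HoxC (q = 0.0390) and HoxD (q = 0.0468) were also below.

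**Figure D2:**
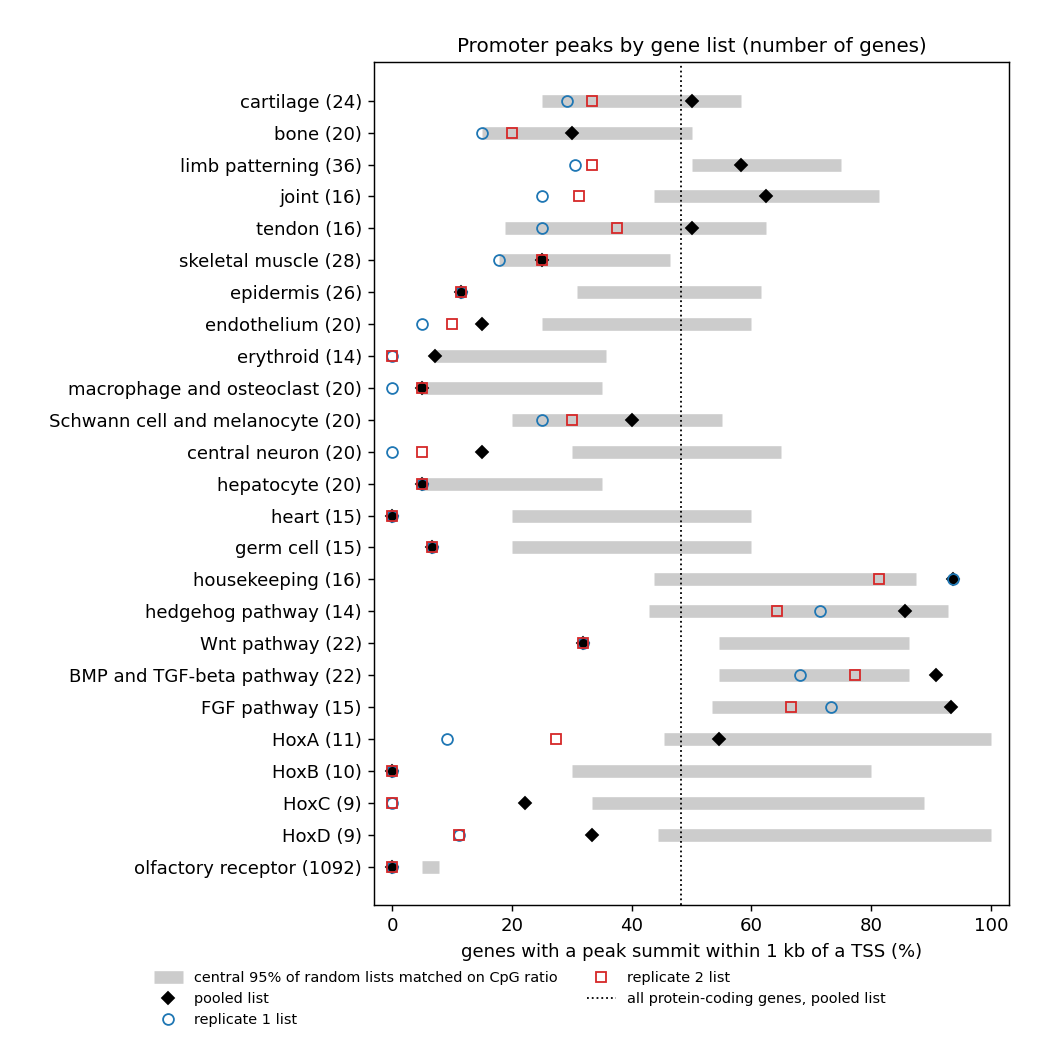
Percent of genes with a promoter summit (horizontal axis) in each of the 25 lists, with the number of genes in parentheses, for the pooled list (diamonds) and the lists of replicate 1 (circles) and replicate 2 (squares). Grey bars give the central 95% of random lists matched on CpG ratio for the pooled list, and the dotted line is 48.2%, the share of all genes.

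Away from promoters, summits of the pooled list were more frequent around genes of 3 signalling pathways. The pooled list held 7844 distal summits, of which 6666 were within 100 kb of a TSS, and 2534 genes had at least 1, with a mean of 0.304 per gene, against 0.113 and 0.164 in the lists of replicates 1 and 2. FGF genes had 2.80 per gene against 0.553 in random lists of matched length (q = 0.009999), hedgehog genes 2.29 against 0.483 (q = 0.0150) and BMP and TGF-beta genes 1.91 against 0.554 (q = 0.0133). These random lists were not matched on promoter summits, which the same 3 lists had at more of their genes than other genes did. These counts are of summits, so a region with several summits counts several times, and counts by region are not given. Fgfr1, an FGF receptor, had 13, which lay in fewer regions, the strongest in an intron at chromosome 8 from 25536035 to 25537997 with a signal of 8.44. Smad7, an inhibitor of TGF-beta signalling, had 10, and Gas1, a hedgehog co-receptor, had 9, the strongest intergenic at chromosome 13 from 60110199 to 60110879. In the lists of replicates 1 and 2, Fgfr1 had 9 and 9, Smad7 4 and 10, and Gas1 1 and 7. In the lists of single replicates, FGF genes had 1.30 ± 0.0471, hedgehog genes 1.36 ± 0.606 and BMP and TGF-beta genes 0.795 ± 0.354 summits per gene (SD, n = 2). With replicate 1's list alone, the FGF list was still called (q = 0.0350), and the hedgehog (q = 0.0962) and BMP and TGF-beta (q = 0.416) lists were not. The hedgehog call was also lost with a limit of 50 kb, and the BMP and TGF-beta call among summits at or above the median signal.

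Bone genes had 1.35 distal summits per gene against 0.403 (q = 0.0560), a difference called with replicate 2's list alone (q = 0.0133) and not with replicate 1's (q = 0.416). In the lists of replicates 1 and 2, bone had 0.45 and 1.1 per gene and cartilage 0.625 and 0.375. The Wnt list had 0.364 and 0.5, skeletal muscle 0.286 and 0.357, and macrophage and osteoclast genes 0.15 and 0.35. The bone, skeletal muscle and Wnt lists were called in the looser pooled list, bone and Wnt without length matching, and cartilage with a limit of 250 kb. Col1a2 had 10, Col1a1 9 and Sp7, an osteoblast transcription factor without a promoter summit, 4. Col1a2 had 2 and 9, Col1a1 6 and 7, and Sp7 0 and 4 in the lists of replicates 1 and 2. Cartilage genes had 0.958 against 0.398 (q = 0.194), with 7 at Wwp2 (7 and 2 in the replicates' lists), 6 at Col11a1 (3 and 2) and 5 at Acan (4 and 2). Skeletal muscle genes had 0.714 against 0.296 (q = 0.201), 8 of them at Mef2c (3 and 2 in the replicates' lists). The Wnt list had 1.36 against 0.526 (q = 0.148), 9 of them at Wnt7b (6 and 4). Macrophage and osteoclast genes had 0.850 against 0.310 (q = 0.194), of which Nfatc1 had 16. Limb patterning had 0.667, joint 0.750, tendon 1.00, epidermis 0.692, endothelium 0.750, erythroid 0.214, central neuron 0.4, hepatocyte 0.200, heart 0.200 and housekeeping 0.750 per gene, none of them called. In single replicates these 10 lists had from 0 to 0.562 per gene. Among them, housekeeping genes stood against 0.189 in random lists of matched length (q = 0.186). That ratio of 3.97 exceeded the 3.45 of the called BMP and TGF-beta list, so a high ratio was not limited to signalling pathways. In the lists of replicates 1 and 2, housekeeping genes had 0.0625 and 0.125 per gene. The HoxB and HoxC lists had 0.200 and 0.111, and the HoxA, HoxD, germ cell, and Schwann cell and melanocyte lists had none. Olfactory receptor genes had 0.0201 against 0.134 (q = 0.00500). Over all genes, most distal summits lay at Sfi1 with 22, Nfatc1 with 16, Tex14 with 15, 2010111I01Rik with 14, Acot11, Fgfr1, Smg6 and Zfp521 with 13, and Bahcc1 and Dnm3 with 12. This order did not hold in single replicates, where Sfi1 had 16 and 10, Nfatc1 3 and 5, Tex14 13 and 15, 2010111I01Rik 4 and 6, Acot11 7 and 7, Smg6 7 and 11, Zfp521 0 and 5, Bahcc1 5 and 7, and Dnm3 5 and 5. The count at Sfi1 is doubtful, because 5 further regions nearest to it passed the score limit and were missing from the thresholded list, against 0 for each of the others.

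**Figure D3:**
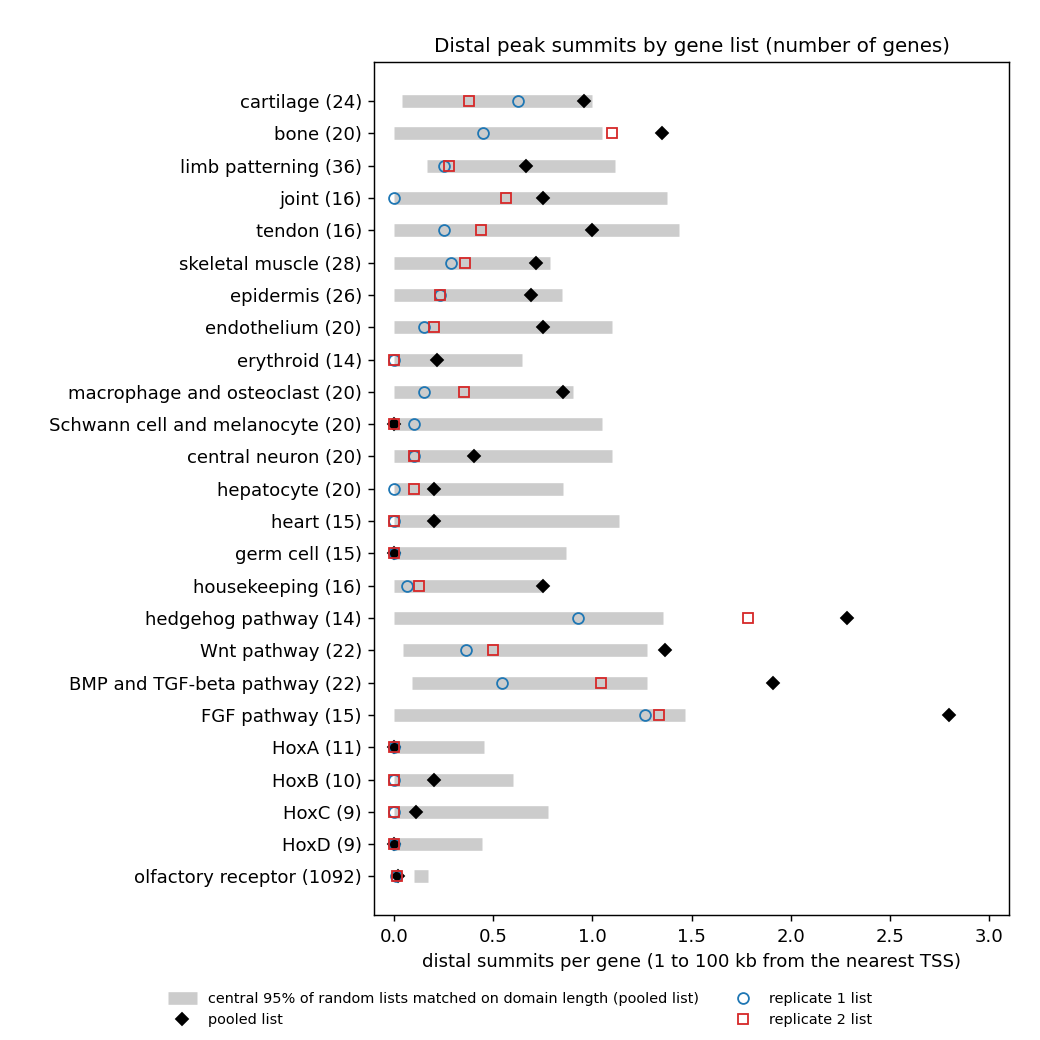
Distal summits per gene (horizontal axis) in each list, for the pooled list (diamonds) and the lists of replicate 1 (circles) and replicate 2 (squares). Grey bars give the central 95% of length-matched random lists for the pooled list, and the diamonds of the FGF, hedgehog, BMP and TGF-beta, Wnt and bone lists lie above them, of which the Wnt and bone lists were not called after adjustment, while the olfactory receptor list lies below its bar.

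The strongest distal peaks were narrow, and all but 1 were intergenic. The strongest lay on chromosome X from 143482935 to 143483180, 246 bp wide with a signal of 55, and its nearest TSS, that of Pak3, was 35531 bp away. The next were on chromosome 2 from 69355470 to 69355735 near Abcb11 with 47.2, on chromosome 10 from 96077546 to 96077951 with 39.7, and on chromosome 2 from 3964425 to 3964690 near Frmd4a with 39.0. The remaining 6 had signals from 24.6 to 37.3, with G6pd2, Galc, Tyrp1, Cldn34d, Nxph1 and Myl12b as nearest genes, and the one at Cldn34d lay in an intron. Of these 10 regions, 5 aligned with the mitochondrial genome over at least 50% of their length and 6 had another nuclear copy of that length.

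Motifs were searched to see which sequence signals lay under the summits. In the 7843 distal windows the CTCF consensus, the site of an insulator protein, was in 0.995% against 0.0510% of GC-matched random windows, a ratio of 19.5 (95% interval 7.14 to 53.2, q = 2.91e-18) that rests on 78 against 4 windows. It was 11.5 in replicate 1's list, 5.14 in replicate 2's and 13 with a background matched on CpG too, chosen after seeing the data. AP1 sites had a ratio of 2.04 (1.63 to 2.56, q = 5.52e-10), TEAD sites 1.59 (1.30 to 1.95, q = 1.99e-05) and RUNX sites, bound by regulators of bone and cartilage, 1.35 (1.11 to 1.65, q = 0.00476). RUNX was not called in either replicate's list (q = 0.200 and 0.0838) and had 1.06 against flanking sequence, and TEAD was not called in replicate 1's (q = 0.283). The E-box variant of MYOD had 1.72 (q = 5.60e-29), that of TWIST 1.25 (q = 5.34e-05) and that of ZEB 0.453 (q = 3.07e-50). CREB sites had 5.30, ETS 2.53, SP/KLF 2.18, MEF2 2.07, NFY 1.44 and the homeodomain core 1.79, all called in the pooled list, while GATA had 0.421 and SOX 0.799. Single replicates gave CREB 31 and 6.40, ETS 8.33 and 14, MEF2 3.4 and 3.1, and the homeodomain core 1.54 and 2.72. Matching on CpG too ended the homeodomain (q = 0.277), SOX (q = 0.589) and NRF1 (q = 0.179) calls, and called TBOX below random windows (0.545, q = 0.0362). NFY turned to 0.852 in the looser pooled list, SOX was not called in the conservative list or in either replicate's (q = 0.265 and 0.558), and GATA and the homeodomain core were not in replicate 1's (q = 0.421 for each). HOX13, with 1.5 (q = 0.178), MEIS, with 1.03 (q = 0.645), and TBOX, with 0.706 (q = 0.290), were not called, nor were CArG with 1.67, HOX-PBX with 2.43 and TCF/LEF with 0.333. NRF1 was called on 11 windows against 1. MEF2 and homeodomain sites were rarer than in flanking sequence, which was not matched on GC content, with ratios of 0.475 and 0.387. TWIST was 0.995 in replicate 1's list.

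In the 24229 promoter windows sites of broadly expressed factors exceeded random windows. CREB sites had a ratio of 23.1 (13.2 to 40.2), ETS sites 17.0 (12.5 to 23.1), NRF1 9.65 (5.86 to 15.9), NFY 3.93 (3.60 to 4.28), CTCF 3.09 (1.93 to 4.94) and SP/KLF 2.12 (1.97 to 2.28). Against flanking sequence CREB had 14.3, ETS 10.5, NRF1 23.4, NFY 3.59, CTCF 4.18 and SP/KLF 11.2, so their order depends on the background. With a background matched on CpG too, chosen after seeing the data, CREB fell to 3.66 and ETS to 10.9, and ETS also exceeded CREB in each replicate's list, with 23.3 against 16.9 and 21 against 20.9. For 8821 of these windows too few random windows of equal GC content existed, and theirs were drawn with replacement. MEF2 had 3.5, HOX13 2.77 and CArG 1.73, but all turned against flanking sequence, to 0.127, 0.340 and 0.646. The flanks were not matched on GC content, and the homeodomain core was in 2.58% of them against 0.165% of GC-matched windows. Turns of such AT-rich motifs against flanks can therefore follow from base composition. HOX13 was not called with CpG matching (1.33, q = 0.190) or in replicate 2's list (q = 0.0634), and MEF2 fell to 1.75 with CpG matching. TEAD, SOX, MYOD, TWIST, ZEB and TBOX sites were rarer than in random windows, with ratios from 0.360 to 0.715. The lowest, that of ZEB, was 0.764 against flanking sequence. With CpG matching TEAD turned to 1.41 (q = 0.00209) and the TBOX call was lost (q = 0.170), as it was in replicate 2's list (q = 0.0970), and MYOD turned to 1.31 against flanking sequence. AP1 and MEIS, not called at promoters in the pooled list (1.14 and 1.08), were called with CpG matching (1.62, q = 8.87e-06 and 1.24, q = 4.72e-07), but had 0.644 and 0.849 against flanking sequence. The NFI, P63 and REST consensuses were in too few distal windows to compare.

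**Figure D4:**
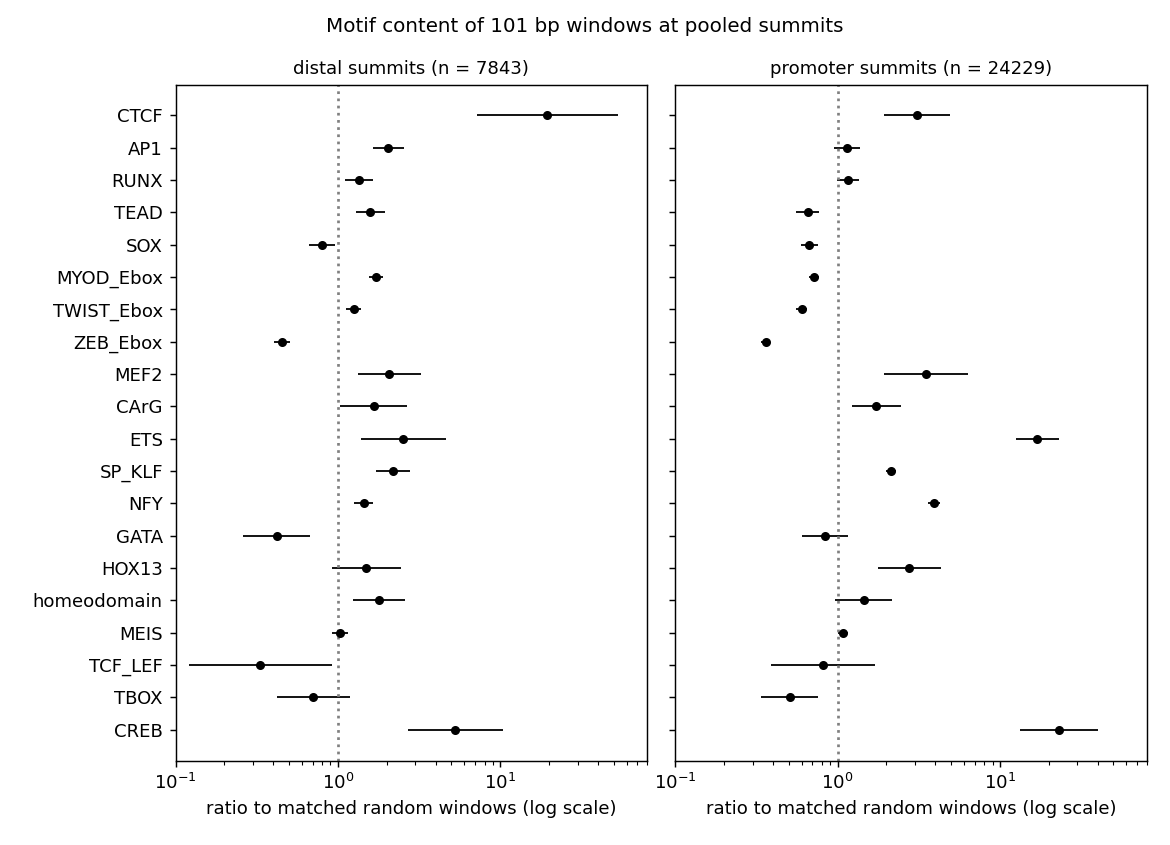
Ratio of windows with each motif at pooled summits to GC-matched random windows, on a log scale, for distal (left) and promoter (right) summits, without motifs found in few windows. Points are ratios with 95% intervals, which do not cover the spread between replicates.

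Regions called in 1 replicate only were less often at promoters. In replicate 1 there were 1049 such regions, 11.2% of its list, and 60.8% of them (57.8 to 63.7) were at promoters, against 85.2% (84.4 to 85.9) of the shared ones. In replicate 2 there were 2302, or 21.9%, with 55.1% (53.0 to 57.1) at promoters against 85.1%. Their median signal was lower, 5.64 against 8.34 within replicate 1's list and 6.15 against 9.49 within replicate 2's. Only 54 of the replicate 1 regions and 329 of the replicate 2 regions were also absent from the other replicate's looser list. Each gene list had from 0 to 7 regions of 1 replicate only nearby. No list was called different between the replicates after adjustment, and counts this small leave most differences undetected.

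Peaks were sparse on the sex chromosomes. The autosomal median was 5.59 regions per Mb of assembled sequence. The X chromosome had 0.421 times that density, and 0.438 ± 0.0190 in the replicates' lists (SD, n = 2), while its density of protein-coding genes was 0.722 times the autosomal median. A promoter summit was found for 312 of 948 X-linked genes, or 32.9%, against 49.4% of the 20780 autosomal genes. Random lists matched on CpG ratio had a mean of 37.6%, with a central 95% from 35.1 to 40.2. The Y chromosome had 0.0142 times the autosomal density. That value rests on 7 pooled regions, with 3 and 5 in the lists of replicates 1 and 2. The density of protein-coding genes on Y was 2.08 per Mb, against 5.80 on X.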

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

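The tests of the reproducibility threshold and of CpG content were chosen after their results were seen, and the others before. A check of −log10 p at equal signal on X was added after the test of promoter signal on X had given its result.

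The ranked lists were used above only for the score limit and for regions missing near the genes with most distal summits. They held summits that passed the score limit of 540 and yet were missing from the thresholded lists. There were 283 for the pooled list, 270 for the conservative list, 213 for replicate 1 and 182 for replicate 2, each above the limit of 3 that a count of 0 allows. Of the 283, 102 lay on scaffolds outside the 21 chromosomes. The others made up 80 regions, of which 53 had another nuclear copy over at least 50% of their length, against 8 of 100 other distal regions. One of them, on chromosome 1 from 24611586 to 24616170, aligned with the mitochondrial genome at 99.956% identity over 100% of its length.

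The 10 strongest distal peaks exceeded the strongest promoter peaks. Of the 10, 5 aligned with the mitochondrial genome over at least 50% of their length, against 0 of the 10 strongest promoter regions and 1 of 100 other distal regions, and another nuclear copy was found for 6, against 0 and 8. These values fit sequence shared with the mitochondrial genome and sequence present in several copies in the nuclear genome, which could draw reads from elsewhere, and 3 of the 10 met neither condition. One of these 3, on chromosome 2 from 69355470, aligned with the mitochondrial genome at 100% identity over 48.5% of its length, and the strength of the other 2 stays unexplained. No biological explanation was tested.

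Replicate 2 had more regions than replicate 1. The authors' threshold is argued against, since the ranked lists before it already had 1.24 times as many summits in replicate 2. The replicates' looser lists were compared at equal signal. At signals from 5 to 6, the median −log10 p of replicate 2 was 1.02 times that of replicate 1 (bootstrap interval 1.01 to 1.04). At signals from 8 to 10 it was 1.09 times. That direction is consistent with deeper sequencing of replicate 2, but the step is small and does not show that depth accounts for the difference in number. The pools also differed in embryos, 78 and 62, which was not tested.

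Fewer X-linked than autosomal genes had a promoter peak, and lower CpG content is argued against as the whole cause, since 32.9% lay below the range of matched lists, from 35.1 to 40.1 in a further draw of random lists. Leaving out, on every chromosome, genes whose symbol stem is shared by 5 or more genes of that chromosome brought the X-linked share to 48.2%, within the matched range from 46.7 to 54.0. Of the 398 X-linked genes left out, 47 had a promoter peak. The stem was the leading letters of a symbol. It thus also joined unrelated genes that share a naming prefix, and all symbols that begin with a digit. Repeated gene families remain a candidate explanation that this rule cannot separate from shared naming. Fewer open X copies per cell cannot be told apart from the rest. For this test the looser pooled list was used. Among X-linked genes with a peak there, the 90th percentile of promoter signal was 0.991 times that of matched autosomal genes (0.951 to 1.04). That met the bound set beforehand against this cause. In a check added afterwards on the same list, −log10 p at equal signal, from 5 to 6, was 0.812 times the autosomal value on X (0.797 to 0.847). The check rests on 111 X summits. The signal value may thus offset a lower number of reads, which could not be tested without read counts. The bound therefore cannot decide.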

How the results depend on the processing

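No paired analysis was possible because the samples form 1 group. The CpG-matched lists, the GC and CpG matched background and the count of 1 summit per region were chosen after seeing the data; the others were fixed before the data were examined. With the conservative list no value below moved, but 4 single calls changed: distal SOX was lost, and HoxC promoters, distal HOX13 and promoter AP1 were gained. The cause of the shifts below was not tested. Unknown depth limits all counts of peaks.

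Counting every row gave 32073 in place of 14150 pooled regions. Replicate overlap (88.8% and 78.1%) became 83.4% and 74.1% with 50% reciprocal overlap, 76.3% and 62.1% with summits within 100 bp, 74.0% and 61.3% with a Jaccard index of 0.4998 in the pseudoreplicated lists, 84.1% and 83.0% with equal list sizes, and for replicate 2 79.2% above the median signal.

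Shares of promoter, exon, intron and intergenic summits (75.5%, 0.963%, 8.44% and 15.1%) became 46.3%, 2.57%, 21.8% and 29.2% in the pseudoreplicated list, 69.3%, 1.86%, 11.5% and 17.3% with a 500 bp window, and 70.7%, 1.12%, 10.5% and 17.7% with 1 summit per region. Exon and intron shares were 0.755% and 7.33% above the median signal, and 0.614% and 7.20% with a 2500 bp window. With either replicate left out the ranges were 81.5% to 84.8%, 0.598% to 0.711%, 4.47% to 5.91% and 10.2% to 11.8%.

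Lists above other genes (4) numbered 1 against CpG-matched lists and 2 to 4 with a replicate left out, and those below (11) numbered 5 in the pseudoreplicated list, where epidermis (65.4%) and central neuron (65.0%) turned direction. Lists with more distal summits (3) numbered 6 in the pseudoreplicated list, 5 without length matching, and 1 to 4 with a replicate left out.

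Among distal motifs, 13 enriched and 3 depleted became 9 to 12 and 1 to 2 with a replicate left out. Depleted distal motifs numbered 5 with longer windows and 7 against flanks, and depleted promoter motifs (6) numbered 15 against flanks. The flanks were not matched on GC content. Ratios that turned were, at distal summits, NFY 0.852 in the pseudoreplicated list, TWIST 0.995 to 1.22 with a replicate left out, MEIS 0.858 with longer windows, and against flanks MEF2 0.475, HOX13 0.672 and homeodomain 0.387. At promoters they were TEAD 1.02 and MEIS 0.828 with longer windows, TEAD 1.41 with GC and CpG matching, and against flanks AP1 0.644, RUNX 0.564, MYOD 1.31, MEF2 0.127, CArG 0.646, HOX13 0.340, homeodomain 0.0927, HOX-PBX 0.119 and MEIS 0.849.

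Regions of 1 replicate only (11.2% and 21.9%, at promoters 60.8% and 55.1%) became 16.6% and 25.9% (68.7% and 59.5%) with 50% reciprocal overlap, 0.578% and 3.13% (46.3% and 41.0%) when absent from the looser list, and 15.9% and 17.0% (replicate 2, 57.7%) with equal list sizes. The X ratio (0.421) became 0.300 in the pseudoreplicated list, 0.458 above the median signal and 0.425 to 0.452 with a replicate left out, and the Y ratio (0.0142) 0.00791, 0.00947 and 0.00938 to 0.0138.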

Other observations

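The gene families in this part were chosen after the lists above were seen, and their tests were adjusted over 17 families. A promoter summit was frequent at several families of basic cell machinery: 77 of 80 cytosolic ribosomal protein genes, 73 of 78 mitochondrial ribosomal protein genes, 40 of 46 NADH dehydrogenase (Nduf) genes and 41 of 50 proteasome (Psm) genes had one. Families were picked by symbol, so the Nduf and Psm sets also hold genes that are not subunits. Each share was above that of CpG-matched random lists, with means of 76.5%, 72.8%, 73.1% and 66.4% (q = 0.000486, 0.000486, 0.0350 and 0.00992). Zinc finger genes named Zfp had 289 of 394, or 73.4%, against 55.2% (q = 0.000486). Histone genes had 59 of 67, within the range of matched lists (q = 0.329).

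Other families had a promoter summit less often than CpG-matched random lists. Wnt ligands had 2 of 19 against a matched mean of 62.7% (q = 0.000486), Fgf ligands 5 of 22 against 48.2% (q = 0.00992), Sox genes 8 of 19 against 74.1% (q = 0.00340), Fox genes 20 of 44 against 67% (q = 0.00212) and potassium channels 16 of 94 against 47.8% (q = 0.000486). Single replicates gave shares of 0% and 0% for Wnt ligands, 13.6% and 13.6% for Fgf ligands, 26.3% and 26.3% for Sox genes, 43.2% and 38.6% for Fox genes, 6.38% and 8.51% for potassium channels and 30.8% and 23.1% for Tbx genes. Collagens, with 19 of 44 against 41.1% (q = 0.929), and Tbx genes, with 6 of 13 against 47.6% (q = 1), were not called. Against all other genes, without matching, Sox (42.1%, q = 0.738) and Fox genes (45.5%, q = 0.812) were not called by Fisher's exact test. Of 53 keratin genes 1 had a promoter summit, and of 326 vomeronasal receptor genes 1, while the 57 keratin-associated protein genes and the 64 defensin genes had none.

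The widest pooled region was 2769 bp, at the start of Nr3c1, the glucocorticoid receptor gene, on chromosome 18 from 39489178 to 39491946. The next widest were 2664 bp at Duxf3, 2460 bp at Dnmt3a, 2321 bp at Msl1, 2278 bp at Fcgr3 and 2232 bp at Nsd1. The Duxf3 region, on chromosome 10 from 58231160 to 58233823, lay close to one from 58223961 to 58226034. The latter passed the score limit, was missing from the thresholded list and had 2 other nuclear copies. Whether copied sequence affected the width at Duxf3 was not tested.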
